A study of Mus musculus with 15 samples.

How the data were processed

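Single-cell RNA sequencing of dissociated striatum was analysed from 15 male C57BL/6J mice, an inbred laboratory strain. The labels place 5 mice in each of 3 groups: placebo, haloperidol from implanted pellets, and olanzapine in food. Treatment lasted 28 to 29 days, after purchase at 8 weeks of age and about 1 week of habituation. Per the labels' protocols, brains were perfused and sliced, the striatum was triturated to single cells, and dead cells were removed. For each mouse, 500 cells were loaded into a separate well of a 10x Genomics Chromium Controller, which barcodes the RNA of single cells in droplets (3' kit, version 2). Each mouse is therefore a separate animal and a separate library. The labels number mice 1 to 15 across the groups and name no batch, so no pairing or batch term was used. Numbers 1 to 4 went to haloperidol and olanzapine mice, and the first placebo mouse is number 5. An effect of that order was not modelled. Replicate numbers used here follow the order of deposit and only name a mouse.

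The deposited table holds counts of unique molecular identifiers (UMIs), whole numbers per gene and cell, for 15932 genes and 5581 cells. Further lines of the same table assign each cell to a mouse, a drug and 1 of 7 cell classes. Per the submitters' processing notes, Cell Ranger, Seurat and the mm10 mouse genome build were used, and versions are not given in the sources used here. All 5581 cells mapped to a mouse, and the drug recorded for each matched the labels. The cells and genes had already been filtered before deposit, since every cell held at least 501 detected genes and every gene was seen in at least 2 cells. Deposited cells held 621 to 40783 UMIs, with a median of 2746. No row without a gene name was used.

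From these counts, cells with under 200 genes or over 20% mitochondrial UMIs were removed, which took out 23 cells for mitochondrial content. Doublets were called per mouse with Scrublet in scanpy 1.11.5 (Python 3.11.15), at its automatic threshold. They numbered 81, or 1.45% of the cells. Of these, 38 came from the 128 cells of olanzapine 2, where the threshold settled at 0.035, and 9 from the 80 cells of olanzapine 1. The 5477 cells left held 18258286 UMIs, with 70 to 1172 cells and 212300 to 4231756 UMIs per mouse. Over the 30 pairs of mice within a group, 0 cells were identical and the chi-square of summed counts per degree of freedom was 1.42 to 6.25, so all 15 mice were counted separately.

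Cell classes are those the authors deposited: astrocyte, microglia, neuroblast, neuron, oligodendrocyte, olig precursor and other. Of 151 fixed marker genes, 132 were in the table. The classes named olig precursor and oligodendrocyte carry each other's markers, as given in the results, so they are written as the class labelled with that name. The cells were also clustered anew with scanpy (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2), and clusters were named only from the fixed markers, at 3 or more markers enriched at least 2-fold. Striatal projection neuron-like and endothelial-like cells taken from those clusters were tested as extra classes.

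Counts were summed per mouse and class, and a mouse entered a class with at least 10 cells there. A comparison was tested in a class with at least 3 such mice in both groups. All groups entered 1 fit per class, with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling and the robust quasi-likelihood F test, which is two-sided. Adjusted p-values are Benjamini-Hochberg values within a class and comparison, at a threshold of 0.05. CPM values are counts scaled by the TMM library size, as edgeR gives them, with the SD over mice. Fold changes carry their standard error (SE). In fits that left out 1 mouse, a class needed at least 2 mice per group, only in pairs tested with all mice.

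The 21 gene lists, the markers, the tests and the alternatives were fixed before the data were examined. Exceptions are those said to be added, set later or outside the plan. A list with at least 5 tested members was tested against all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists and classes within a comparison. An estimated correlation and fry were the alternatives. No list call held with either of them in any comparison. Marker lists were tested by camera as well, outside the fixed plan, and adjusted over marker lists and classes within a comparison. Medians of a list are over its tested members. Shares of cells per mouse were compared by exact two-sided permutation of mice (scipy 1.17.1), adjusted over the 7 classes.

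Genes were named by a fixed rule. It takes, per class, up to 6 called genes with the largest fold change and a mean log2 CPM of at least 5, and up to 4 members of each called list with the smallest p. It adds markers and response genes of projection neurons at any p and, with fewer than 10 calls, the 10 gene and class pairs with the smallest p. Csrp1, Myl9, Ptk2 and, for olanzapine, Tmsb10 fall outside it and were named after their values were seen, to complete the higher and lower calls; 1 called gene and 1 marker gene are not reported here. Gene positions are from GENCODE M21 on GRCm38, which is mm10, and all 181 named genes matched it by symbol.

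The steps were tested on simulated counts drawn from the real means and library sizes of astrocytes, neurons and the class other, with 200 genes changed. With 4-fold changes, 83.3 to 92.4% of changed genes were recovered in neurons and the class other for haloperidol against placebo. For olanzapine against placebo the share was 87.9 to 97%, and for haloperidol against olanzapine 87.9 to 93.9%. In astrocytes it was 95.5 to 97%. With 2-fold changes it was 28.4% in neurons and 37.3% in the class other for haloperidol against placebo, 29.9 and 34.3% for olanzapine against placebo, and 31.3 and 28.4% for haloperidol against olanzapine. False calls numbered 2 to 7 per fit. A list of 30 members raised 1.3-fold was called in all 9 simulated fits, with 0 unchanged lists called. Those lists were random and their genes were drawn independently, so this does not cover lists whose genes move together.

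Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, only the compared groups in the fit, at least 20 cells per mouse and class, and a stricter cell filter (at least 500 genes and at most 10% mitochondrial UMIs). Further ones were doublets kept, clusters in place of deposited classes, no classes, genes likely to be free RNA left out, adjustment over all classes, at least 1.5-fold changes, and leaving out each mouse. Added after seeing the data were clusters at resolution 1, leaving out the 4 mice with the fewest cells and leaving out smooth muscle cells. Also added were the extra classes above as the only class, and the share of cells typed as endothelial by fixed markers as a covariate. The planned test of whether a drug acts differently on direct- and indirect-pathway projection neurons was not run, since only 4 placebo, 2 haloperidol and 2 olanzapine mice had 10 cells of both. The class labelled olig precursor was not tested for haloperidol, with 2 mice.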

Results

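Gene expression was measured in single cells of the striatum, the main input nucleus of the basal ganglia and a principal site of action of antipsychotic drugs, after 28 to 29 days of treatment. The labels assign 5 mice to haloperidol, a typical antipsychotic that blocks dopamine receptors. Another 5 received olanzapine, an atypical antipsychotic that blocks serotonin and dopamine receptors, and 5 received placebo. The design asks which cells and genes of the striatum differ between each drug and placebo, and between the drugs. Haloperidol came from a pellet and olanzapine in food, so the route of delivery differed together with the drug.

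The 5477 cells analysed held 18258286 UMIs. Astrocytes (1605 cells), neurons (959), microglia (886) and neuroblasts (704) were the most numerous classes, followed by the class other (523), the class labelled oligodendrocyte (450) and the class labelled olig precursor (350). Depth was uneven, from 212300 UMIs in 70 cells of olanzapine 1 to 4231756 UMIs in 1172 cells of olanzapine 3. The 4 mice with the fewest cells were haloperidol 1 (122), haloperidol 2 (91), olanzapine 1 (70) and olanzapine 2 (90), and no placebo mouse fell below 165. These 4 mice carry the numbers 1 to 4 in the labels, which name no batch, and of them only haloperidol 2 entered the tests of the class other, which held all called genes. Without the 4 mice, a setting chosen after seeing the data, 3 genes were called with haloperidol and 23 with olanzapine against placebo, including 2 of the 2 and 10 of the 10 called with all mice. Of the called lists, 7 of 15 and 13 of 24 were called without them as well. The median mitochondrial share was 3.15% ± 0.788 with haloperidol, 2.95% ± 0.455 with olanzapine and 2.38% ± 0.357 with placebo (SD, n = 5 each; exact two-sided permutation p = 0.0635 for each drug against placebo).

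Markers fixed in advance placed most deposited classes. Microglia carried P2ry12 (3001 CPM), astrocytes Aldoc (4462 CPM) and neurons the projection neuron peptide genes Penk (4370 CPM) and Tac1 (3155 CPM). The class labelled olig precursor carried the myelin genes Mbp (8354 CPM) and Mog (2564 CPM), whereas the class labelled oligodendrocyte carried the precursor genes C1ql1 (1255 CPM) and Pdgfra (902 CPM). Cells of the class other were vascular: by new clustering at resolution 1, 264 were endothelial-like, 109 pericyte-like, 98 smooth muscle-like (43 at resolution 2) and 52 fibroblast-like.

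With haloperidol, Tmsb10 fell in the vascular class other. Tmsb10, which encodes an actin-binding thymosin (chromosome 6, 72957347 to 72958748), fell from 3174 ± 480 CPM with placebo (SD, n = 5) to 1421 ± 408 CPM with haloperidol (SD, n = 4), a log2 fold change of -1.14 ± 0.21 (SE, edgeR adjusted p = 0.0341). Every haloperidol mouse lay below every placebo mouse for this gene, which was called from the same mice, so this is not separate evidence. In the same class, cells typed as smooth muscle by 4 fixed markers made up 12.6% ± 8.45 with haloperidol (SD, n = 4) and 3.42% ± 2.46 with placebo (SD, n = 5; exact two-sided permutation p = 0.00794), and the median of these markers was 1.23 higher on the log2 scale. That p is unadjusted and is the smallest that the 126 splits of these mice can give. The test of this share was not in the fixed plan.

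Over 6 classes and 20576 tests, edgeR called 2 genes for haloperidol against placebo. DESeq2 also called 2, and 819 tests had an unadjusted p under 0.05, where 1029 are expected by chance. The nearest pairs that did not pass included Rgs2 in microglia (log2 fold change -0.94), a regulator of G protein signalling, and Psmb5 in microglia (-1.09), a proteasome gene. Tmsb10 was not called without haloperidol 3 (adjusted p = 0.125), haloperidol 4 (0.107), haloperidol 5 (0.0568), placebo 1 (0.0854), placebo 2 (0.0553), placebo 3 (0.129) or placebo 5 (0.134), with log2 fold changes of -1.074 to -1.225 in these fits, and the count of called genes was 0 without haloperidol 3 or 4 and 1 without any of the other 5. The count was 0 with at least 20 cells per mouse, with new clusters and with all cells of a mouse summed, and 7 without a filter on low counts.

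Gene lists moved in several classes with haloperidol at the preset correlation. Ribosomal protein genes, the structural genes of the ribosome, rose in microglia (79 of 80 higher, median log2 fold change 0.24, n = 3 against 5, adjusted p = 1.21e-16). They fell in the class other, whose makeup also differed (78 of 80 lower, -0.35, n = 4 against 5, adjusted p = 2.18e-20). Both had an adjusted p = 0.697 with an estimated correlation. Genes encoded by the mitochondrial genome rose in neuroblasts (12 of 12 higher, 0.36, n = 5 each, adjusted p = 1.43e-06; adjusted p = 0.697 with an estimated correlation), led by mt-Nd2 (0.64 ± 0.21) and mt-Co1 (0.45 ± 0.19), beside the higher mitochondrial share given above and higher fixed markers of cycling progenitors in that class (median 0.43). Clock genes, which drive and follow the daily rhythm, rose in astrocytes (9 of 9 higher, 0.28, n = 5 each, adjusted p = 0.00577; adjusted p = 0.469 with an estimated correlation), led by Cry2 (0.54 ± 0.27) and Clock (0.70 ± 0.38). Cytosolic heat shock genes, which encode chaperones, fell in the class labelled oligodendrocyte (8 of 9 lower, -0.36, n = 4 each, adjusted p = 0.00495; adjusted p = 0.697 with an estimated correlation), led by Hsp90aa1 (-0.60 ± 0.21).

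Homeostatic microglial genes, a signature of resting microglia, were lower in microglia with haloperidol (10 of 12 lower, median -0.26, n = 3 against 5, adjusted p = 0.00228; adjusted p = 0.697 with an estimated correlation). Olfml3 was at -0.57 ± 0.20 and Fcrls at -0.46 ± 0.18. Without haloperidol 3 this list was not called (adjusted p = 0.176). Interferon response genes fell in the class other (11 of 11 lower, median -0.44, n = 4 against 5, adjusted p = 0.00206; adjusted p = 0.697 with an estimated correlation), with Ifit1 at -1.18 ± 0.45, and were not called without haloperidol 3 (adjusted p = 0.101); the makeup of this class also differed, as given above. In all, 15 of 71 list and class pairs were called, 4 up and 11 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.469. In each list named for haloperidol, 0 members passed over all genes tested and 0 adjusted over the list alone. The count of lists without 1 mouse ran from 10 to 22. Dopamine signalling and striatal neuropeptide genes in neurons were not called (15 of 27 higher, n = 5 each, adjusted p = 0.932), with a median log2 fold change of 0.05 and a mean of -0.04, the direction of the test.

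With olanzapine, 6 genes were called as higher in the class other. Csrp1, a LIM-domain gene of smooth muscle (chromosome 1, 135720061 to 135752232), rose from 236 ± 45.4 CPM with placebo (SD, n = 5) to 574 ± 135 CPM (SD, n = 3), a log2 fold change of 1.31 ± 0.22 (SE, adjusted p = 0.0177). Myl9, the regulatory light chain of smooth muscle myosin (chromosome 2, 156775420 to 156781658), rose from 1672 ± 342 to 3763 ± 653 CPM (1.17 ± 0.23, adjusted p = 0.0312). Lmod1, which starts actin filaments in smooth muscle (chromosome 1, 135324807 to 135368065), rose from 69.8 ± 27.6 to 196 ± 5.24 CPM (1.46 ± 0.30, adjusted p = 0.0312). Filip1l also rose (chromosome 16, 57353093 to 57573126; 1.53 ± 0.31, adjusted p = 0.0312). So did the focal adhesion kinase gene Ptk2 (chromosome 15, 73205102 to 73423280; 1.22 ± 0.25, adjusted p = 0.0312) and the membrane oestrogen receptor gene Gper1 (chromosome 5, 139423151 to 139427800; 1.32 ± 0.29, adjusted p = 0.0445). Cells typed as smooth muscle by the 4 markers made up 12.3% ± 2.21 of this class with olanzapine (SD, n = 3; exact two-sided permutation p = 0.0179 against placebo), and the median of these markers, of which Myl9 is 1, was 1.65 higher. The p is again unadjusted and is the smallest that 56 splits can give.

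Vwf, the clotting glycoprotein of endothelial cells (chromosome 6, 125546774 to 125686679), fell in the class other from 405 ± 158 CPM with placebo (SD, n = 5) to 96.4 ± 19.8 CPM with olanzapine (SD, n = 3), a log2 fold change of -1.96 ± 0.35 (SE, adjusted p = 0.0184). Slc38a5, an amino acid transporter gene (chromosome X, 8271133 to 8280179), fell from 455 ± 76.0 to 155 ± 118 CPM (-1.78 ± 0.37, adjusted p = 0.0312). Tmsb10, which fell with haloperidol as well, fell to 1418 ± 302 CPM (-1.18 ± 0.23, adjusted p = 0.0312). The 7 fixed endothelial markers had a median of -0.25 in this class. Olanzapine and placebo mice did not overlap for any of these genes, which were called from the same mice, so this is not separate evidence.

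**Figure D1:**
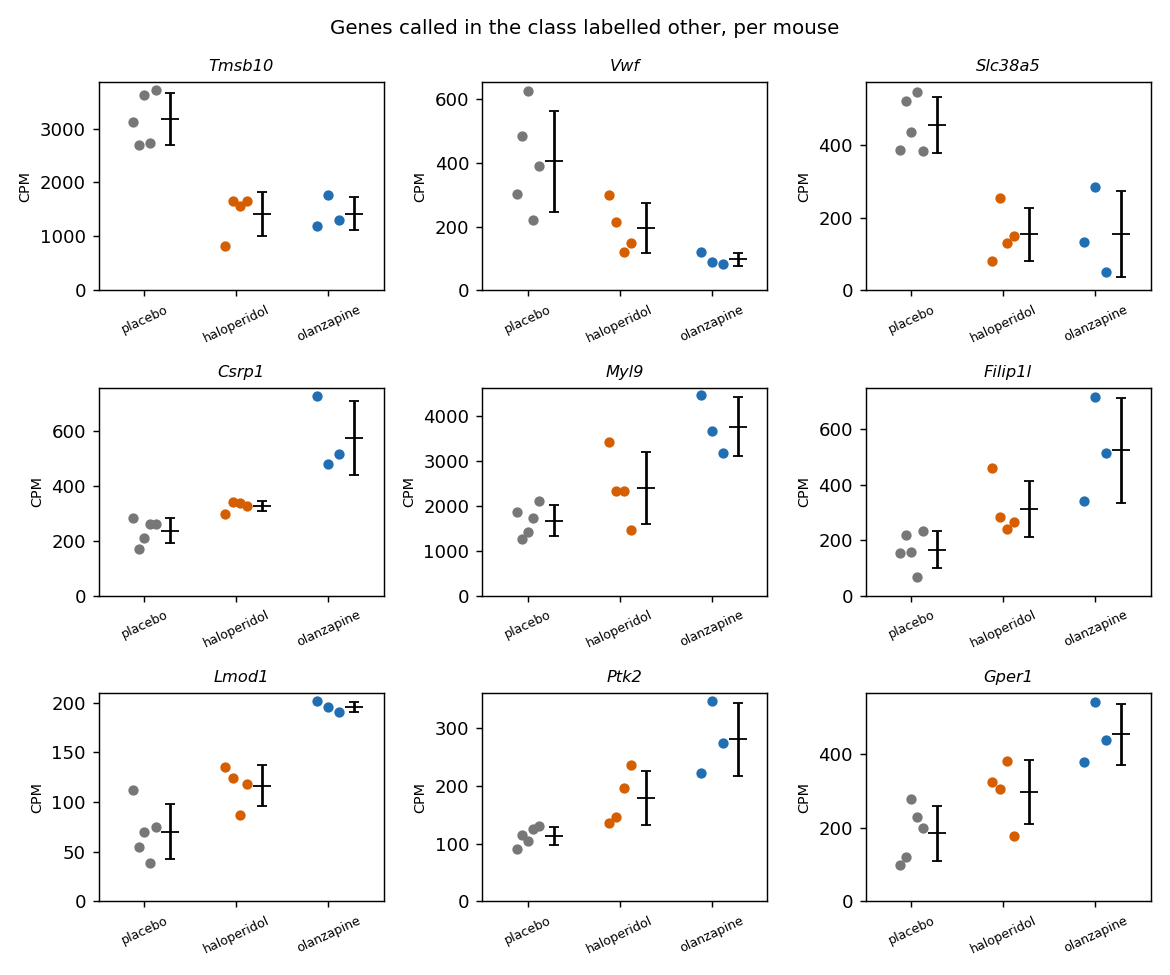
Expression of 9 genes called with olanzapine against placebo in the class other, in CPM per mouse (vertical axes start at 0), with 5 placebo, 4 haloperidol and 3 olanzapine mice. Points are mice, black dashes are means and error bars are SD; Tmsb10 is lower with both drugs, at 3174 CPM for placebo, 1421 for haloperidol and 1418 for olanzapine.

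In all, edgeR called 10 genes, 6 higher and 4 lower, for olanzapine against placebo over 7 classes and 23278 tests. Over all classes 959 tests had an unadjusted p under 0.05, where 1164 are expected by chance, and in the class other 305, where 160 are expected. DESeq2 called 17, of which 9 are shared. The count was 0 without olanzapine 3 or placebo 2, 2 without olanzapine 5, 3 without olanzapine 4, 5 without placebo 5 and 20 without placebo 4; Vwf, for instance, had an adjusted p of 0.0916 without olanzapine 3 (log2 fold change -2.21), and Filip1l 0.0593 (1.81). It was also 0 when adjusted over all classes, with all cells of a mouse summed, with new clusters at resolution 0.5 and with 38 cells typed as smooth muscle by 3 markers, without Myl9, left out of the class. With doublets kept 5 genes were called, 1 higher and 4 lower, and 3 of them were among the 10.

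Immediate early genes, which cells induce within minutes of a stimulus, rose with olanzapine in the class other (14 of 15 higher, median log2 fold change 0.59, n = 3 against 5, adjusted p = 3.11e-06; adjusted p = 0.447 with an estimated correlation). The makeup of this class differed as well, as given above. By edgeR 0 members passed over all genes tested, whereas DESeq2 called Fos (adjusted p = 0.0402) and Egr1 (0.0456). Adjusted over the list alone 5 passed by edgeR, among them Egr1 (1.16 ± 0.26), Fos (1.07 ± 0.25) and Nr4a1 (1.68 ± 0.51). In neurons the list also rose (10 of 10 higher, 0.42, n = 5 each, adjusted p = 0.00153; adjusted p = 0.447 with an estimated correlation). There 0 members passed over all genes tested and 2 adjusted over the list alone, Egr4 (1.40 ± 0.45) and Egr3 (1.25 ± 0.44). The call in neurons was lost without olanzapine 3 (adjusted p = 0.0697) or placebo 4 (0.0602). Neuron scores of single mice, the mean log2 CPM of 4 members, overlapped (6.378 to 8.075 with olanzapine, 6.702 to 7.474 with placebo). Olanzapine 2 and olanzapine 5 lay below every placebo mouse. Cytosolic heat shock genes rose in microglia (8 of 9 higher, 0.23, n = 5 each, adjusted p = 0.00103; adjusted p = 0.362 with an estimated correlation). Of these, 0 passed over all genes tested and 2 adjusted over the list alone, Dnaja1 (0.70 ± 0.21) and Hspa8 (0.54 ± 0.18).

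In neuroblasts, genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, rose with olanzapine (6 of 7 higher, median 0.46, n = 4 against 5, adjusted p = 3.01e-04; adjusted p = 0.254 with an estimated correlation). The chaperone genes Calr (0.83 ± 0.25) and Pdia3 (0.74 ± 0.28) were the 2 that passed adjusted over the list alone, and 0 passed over all genes tested. Fixed markers of cycling progenitors were also higher in neuroblasts in these mice (median 0.44). Clock genes rose in astrocytes (8 of 9 higher, 0.35, n = 5 each, adjusted p = 0.00135; adjusted p = 0.254 with an estimated correlation), with Dbp at 0.62 ± 0.25 and Hlf at 0.61 ± 0.26. Ribosomal protein genes fell in the class other (79 of 80 lower, -0.32, adjusted p = 4.49e-12; adjusted p = 0.706 with an estimated correlation), where the makeup of the class also differed, as given above.

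Neurons of olanzapine mice had higher genes for glutamate receptors and synapses (16 of 21 higher, median 0.22, n = 5 each, adjusted p = 0.00456; adjusted p = 0.447 with an estimated correlation), with the AMPA receptor genes Gria1 at 0.65 ± 0.26 and Gria4 at 0.92 ± 0.38. Mitochondrially encoded genes rose (12 of 13 higher, 0.50, adjusted p = 3.57e-06; adjusted p = 0.447 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell (69 of 83 lower, -0.18, adjusted p = 1.39e-05; adjusted p = 0.706 with an estimated correlation). The mitochondrial share of these mice was 2.95%, against 2.38% with placebo. Of these 3 lists and the clock and ribosomal lists, 0 members passed over all genes tested or adjusted over the list alone. Fixed markers shared by both kinds of projection neuron were also higher in neurons of these mice, uncalled (7 of 8 higher, median 0.24, camera adjusted p = 0.216). Myelin genes, which ensheathe axons, fell in the class labelled oligodendrocyte (5 of 5 lower, -1.06, n = 3 against 4, adjusted p = 3.01e-04; adjusted p = 0.447 with an estimated correlation), with 0 members passing either way and the call lost without olanzapine 5 (adjusted p = 0.0705). Fixed astrocyte markers were higher in that class (5 of 6 higher, median 0.25, adjusted p = 0.0437; adjusted p = 0.393 with an estimated correlation). Those of newly formed oligodendrocytes were lower (7 of 7 lower, -0.32, adjusted p = 0.0437; adjusted p = 0.628 with an estimated correlation).

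In all, 24 of 83 list and class pairs were called for olanzapine, 14 up and 10 down. With an estimated correlation 0 were called, where the smallest camera adjusted p was 0.254. Of 100 splits of these mice, the real one included, 18 called 24 or more. Dopamine signalling and striatal neuropeptide genes in neurons were not called (18 of 27 higher, n = 5 each, adjusted p = 0.693), with a median of 0.08, the direction of the test, and a mean of -0.03. In projection neuron-like cells 0 genes passed for either drug by edgeR, and DESeq2 was not run on them. Unadjusted edgeR p-values under 0.05 numbered 106 for haloperidol and 234 for olanzapine, where 177 are expected by chance for each. These cells pool direct- and indirect-pathway neurons, and 5 placebo, 2 haloperidol and 3 olanzapine mice held at least 10 direct-pathway cells. The share of direct-pathway cells among them was not tested. Tac1, the substance P precursor gene of direct-pathway neurons, was at -0.73 with haloperidol (adjusted p = 0.998) and -0.74 with olanzapine (adjusted p = 0.756), and Pdyn, the dynorphin precursor gene, at -0.67 and -0.89 with the same adjusted p-values. The dopamine receptor genes Drd1 and Drd2, as well as Penk and Adora2a, did not pass for either drug.

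**Figure D2:**
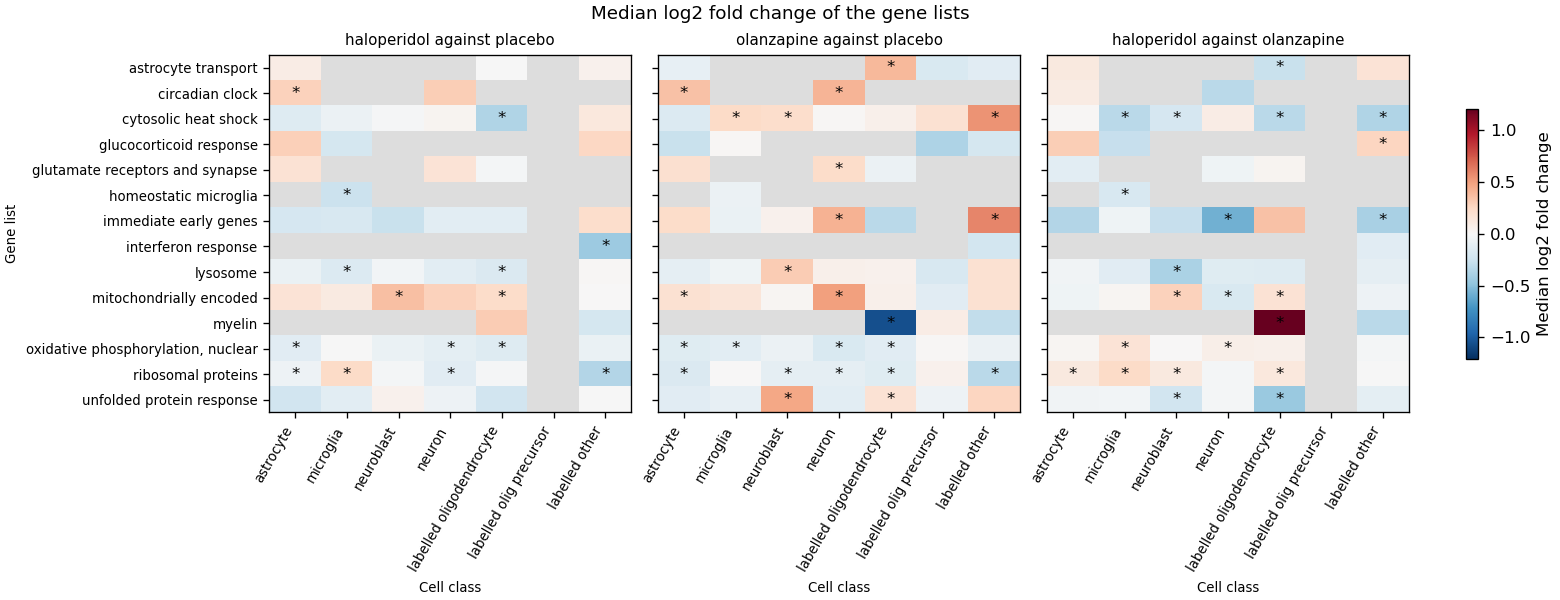
Median log2 fold change of the members of the 14 gene lists called in at least 1 class (vertical axis) in each cell class (horizontal axis) for the 3 comparisons; grey marks pairs not tested, and an asterisk an adjusted p under 0.05 by camera with a preset correlation. Of these calls 15, 24 and 22 were made for haloperidol against placebo, olanzapine against placebo and haloperidol against olanzapine, and 0 with an estimated correlation.

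Between the drugs, immediate early genes were called as a list in neurons. They were lower with haloperidol than with olanzapine (10 of 10 lower, median log2 fold change -0.58, n = 5 each, adjusted p = 8.24e-07; adjusted p = 0.356 with an estimated correlation), and Egr4 (-1.76 ± 0.46) passed adjusted over the list alone, with 0 members over all genes tested. Neuron scores of single mice over 4 members overlapped, at 6.251 to 7.594 with haloperidol and 6.378 to 8.075 with olanzapine. Heat shock genes were lower in microglia (9 of 9 lower, -0.32, n = 3 against 5, adjusted p = 0.00333; adjusted p = 0.356 with an estimated correlation), with Hspa8 (-0.64 ± 0.21) passing adjusted over the list alone and 0 members over all genes. Ribosomal protein genes were higher in microglia (78 of 80 higher, 0.23, adjusted p = 1.06e-11; adjusted p = 0.742 with an estimated correlation). Mitochondrially encoded genes were higher in neuroblasts (12 of 12 higher, 0.28, n = 5 against 4, adjusted p = 2.44e-04; adjusted p = 0.640 with an estimated correlation). Unfolded protein response genes were lower in the class labelled oligodendrocyte (12 of 13 lower, -0.45, n = 4 against 3, adjusted p = 2.11e-04; adjusted p = 0.356 with an estimated correlation). For these last 3 lists 0 members passed over all genes tested or adjusted over the list alone.

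By edgeR, 0 genes were called over 6 classes and 20576 tests for haloperidol against olanzapine, with 714 at an unadjusted p under 0.05 where 1029 are expected, and DESeq2 called 0. The nearest pairs were led by Pcbp4, an RNA-binding protein gene (log2 fold change 1.28, adjusted p = 0.588). Without olanzapine 5 the count was 1, and without a filter on low counts 8. In all, 22 of 71 list and class pairs were called, 10 up and 12 down. With an estimated correlation 0 were called, where the smallest camera adjusted p was 0.356. Of 100 splits of these mice, the real one included, 27 called 22 or more. The count of lists was 14 without haloperidol 3 or olanzapine 4.

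Fold changes of the 2 drugs against placebo were compared across genes in 6 classes, since both share the placebo mice. Across genes, which are not independent replicates, their correlation averaged 0.487 (0.309 to 0.660), against 0.446 in simulated groups with no change that shared the same controls. Genes were simulated independently of each other, so the simulated range holds no genes that move together and no shift in makeup. The covariance averaged 0.0544, against 0.0470 simulated. With the placebo mice split between the comparisons the correlation averaged 0.0459. In the vascular class other the correlation was 0.526 against 0.363 simulated (highest 0.402), 0.219 with split placebo mice, and the covariance was 0.102 against 0.0495. Smooth muscle markers were higher there with both drugs (medians 1.23 and 1.65), so a shared shift in makeup cannot be told apart from a shared drug effect. In neurons the correlation was 0.660 against 0.522 simulated (highest 0.541), 0.0741 with split placebo mice, and the covariance 0.0701 against 0.0591. The class labelled oligodendrocyte was below the simulated values, with a correlation of 0.309 against 0.398 and a covariance of 0.0350 against 0.0496. Microglia were below them too, at 0.413 against 0.455 and 0.0381 against 0.0424. In neuroblasts the covariance was below (0.0368 against 0.0391) and the correlation above (0.509 against 0.461).

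Shares of cell classes varied widely between mice. The class other made up 5.46% ± 3.90 of cells with olanzapine and 11.8% ± 3.01 with placebo (SD, n = 5 each; exact two-sided permutation p = 0.0159, adjusted p = 0.111 over 7 classes). The class labelled oligodendrocyte made up 5.48% ± 3.57 and 10.4% ± 2.79 (exact p = 0.0476, adjusted p = 0.167). Neither passed after adjustment. Both stood at 0% in olanzapine 2, where the doublet caller had removed all their cells, and with doublets kept neither had an exact p under 0.05. Microglia made up 20.2% ± 7.26 with olanzapine, 11.6% ± 5.72 with haloperidol and 15.1% ± 3.76 with placebo, and no class share had an exact p under 0.05 for haloperidol against placebo or against olanzapine.

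**Figure D3:**
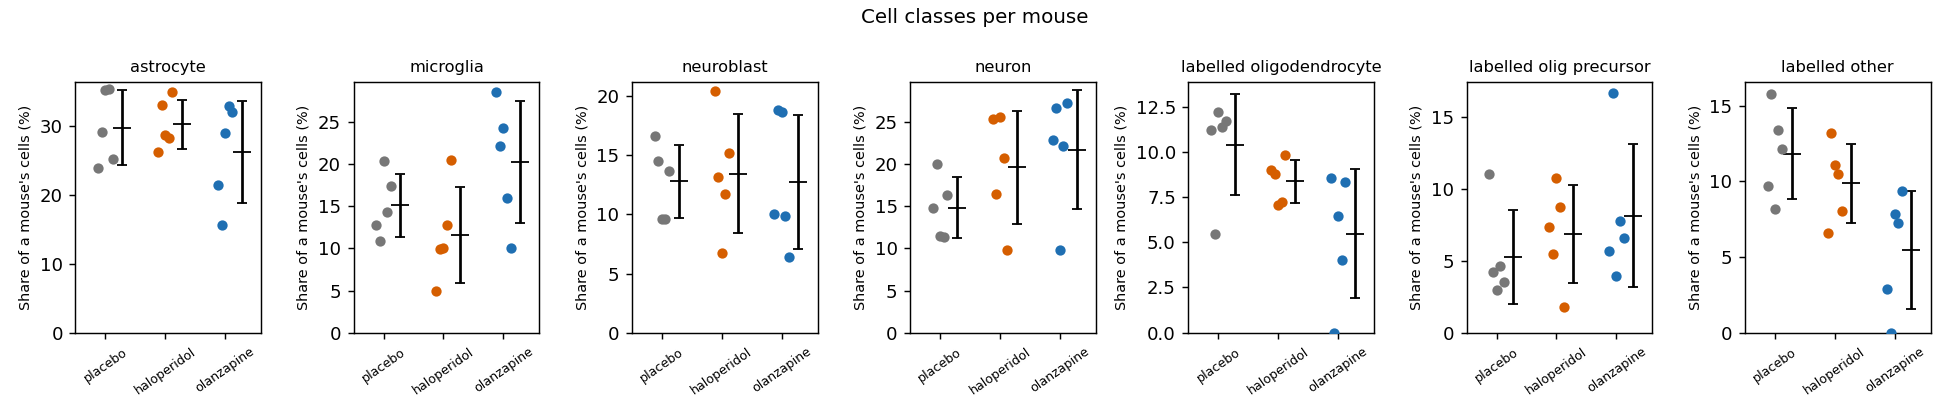
Share of each of the 7 cell classes in each mouse, in percent of its cells, for 5 placebo, 5 haloperidol and 5 olanzapine mice. Points are mice, black dashes are means and error bars are SD; the class other averages 11.8% with placebo, 9.87% with haloperidol and 5.46% with olanzapine, with overlapping ranges.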

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

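Of the tests in this part, those for endothelial cells, for Gper1 and Ptk2 apart and for the smooth muscle share between the drugs were chosen after the result was seen. In 86 groups of 4 or 5 mice, 9 held a mouse far from the others of its group, and chance marks about 1 in 20 groups. CPM values in the next paragraph are scaled by the raw total of the class, without TMM factors.

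The class labelled olig precursor made up 11.01% of the cells of placebo 1, against 2.96 to 4.66% in the other placebo mice. The class labelled oligodendrocyte made up 5.45% in placebo 2, against 11.24 to 12.22% in the others. In the class other, haloperidol 2 stood apart for Filip1l (382.5 CPM, others 207.8 to 236.0) and for Tmsb10 (674.9 CPM, others 1350 to 1378). In projection neuron-like cells, the adenosine receptor gene Adora2a was at 1034 CPM in placebo 3 (others 602.4 to 683.7) and 1174 CPM in olanzapine 2 (others 331.3 to 470.4). Drd2 was at 395.4 CPM in haloperidol 5 (others 158.1 to 203.5), Egr1 at 663.8 CPM in olanzapine 1 (others 118.6 to 222.0) and Nr4a1 at 183.2 CPM in placebo 3 (others 0 to 51.12). Haloperidol 2 and olanzapine 1 and 2 are among the 4 mice with the fewest cells.

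The 10 genes called with olanzapine in the class other moved beside a higher share of smooth muscle cells, so the makeup of the class may account for part of them. The mean share was similar with haloperidol by the 4 fixed markers (12.6% ± 8.45 against 12.3% ± 2.21, SD, exact p = 0.971). It rests on 2 to 10 such cells per drug-treated mouse, and haloperidol 2 (3 of 12 cells) raised the haloperidol mean. So few mice cannot show that the shares are equal. With haloperidol the 6 higher genes were at 0.473 to 0.812 and 0 of them were called. The 4 smooth muscle markers also rose less there (median 1.23 against 1.65), so this comparison does not separate makeup from drug. A smaller share of endothelial cells as a whole is argued against for the 4 lower genes: the 7 endothelial markers had a median log2 fold change of -0.245, against -1.64 for those genes, and within endothelial-like cells Vwf was at -1.62 ± 0.48, Slc38a5 at -1.52 ± 0.37 and Tmsb10 at -1.06 ± 0.34. Cells typed as endothelial made up 48.77% ± 11.16 of the class with olanzapine and 65.45% ± 16.36 with placebo (SD, exact p = 0.196). Among endothelial-like cells 0 lower genes were called, and a shift among kinds of endothelial cell was not tested. With the 38 cells typed as smooth muscle by Acta2, Tagln and Myh11 left out, the 6 higher genes went from a median of 1.32 to 0.853, with Csrp1 at -0.04 ± 0.41, Myl9 at 0.55 ± 0.34, Filip1l at 0.85 ± 0.38, Gper1 at 1.37 ± 0.33 and Ptk2 at 1.35 ± 0.28, and Lmod1 was no longer tested. That median lies too near the bound set for it, given the median standard error of 0.34 of the 5 genes. For Gper1 and Ptk2 a larger smooth muscle share is argued against, since their folds did not fall (from 1.32 ± 0.29 and 1.22 ± 0.25, to no less than 1.35) when Csrp1 lost its own. Gper1 was instead among the 10 top genes of the pericyte-like cluster. Cells typed as pericytes made up 33.7% ± 8.38 with olanzapine and 24.1% ± 12.3 with placebo (SD, exact p = 0.268), and the pericyte markers had a median of 0.04. Whether a larger pericyte share accounts for either gene was not tested. For the other 4 higher genes a larger smooth muscle share cannot be told apart from a change within smooth muscle cells, which leaving those cells out removes as well. The count fell to 0 without those cells. The folds of Gper1 and Ptk2 held, but their adjusted p rose to 0.173 and 0.103. The unadjusted edgeR p rose for Gper1 (1.39e-04 to 3.99e-04) and fell for Ptk2 (8.4e-05 to 6.79e-05), so for Ptk2 the change lay in the adjustment. An effect of olanzapine on the vascular cells themselves stays open.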

How the results depend on the processing

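Results under clusters at resolution 1, without the 4 mice with the fewest cells and without smooth muscle cells were chosen after seeing the data. So were those in a single extra class and with the share of cells typed as endothelial as a covariate. The cause was not tested for any change unless named. For haloperidol against placebo, the 2 calls stayed 2 with DESeq2, RLE scaling, the stricter cell filter, doublets kept and free RNA genes left out. A 1.5-fold minimum also kept 2, but it could not do otherwise, since both changes were larger. The stricter filter acted only through its mitochondrial limit, since every deposited cell held at least 501 genes. The 2 calls became 7 without a filter on low counts, 1 with only the compared groups and 0 with at least 20 cells per mouse and class. They were 0 with new clusters at resolution 0.5, 1 or 2, 0 with all cells of a mouse summed and 1 when adjusted over all classes. They were 1 with the share of cells typed as endothelial as a covariate and 1 without smooth muscle cells. They were 0 in projection neuron-like or endothelial-like cells alone, where fewer genes were tested. Leaving out each mouse gave 0 to 2.

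For olanzapine against placebo, the 10 called genes became 17 with DESeq2, 70 without a filter, 19 with only the compared groups, 20 with at least 20 cells and 5 with doublets kept. They were 0, 1 and 1 with clusters at resolution 0.5, 1 and 2, 0 with all cells summed, 0 when adjusted over all classes and 23 without the 4 mice with the fewest cells. They were 1 with the share of cells typed as endothelial as a covariate (Vwf, edgeR adjusted p = 0.0281) and 0 without smooth muscle cells. Alone, projection neuron-like cells gave 0 and endothelial-like cells 1. The covariate left the log2 fold changes of the called genes at a similar size. Higher genes were at 1.08 (Gper1, from 1.32) to 1.51 (Lmod1), against 1.17 to 1.53 without it. Lower genes were at -1.15 (Tmsb10) to -2.22 (Vwf), against -1.18 to -1.96 without it. The share of smooth muscle cells was not a covariate, so these folds do not separate that difference in makeup from drug. Leaving out each mouse gave 0 to 20. For haloperidol against olanzapine the count was 8 without a filter and 0 to 1 with each mouse left out.

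Called lists fell to 0 in each comparison with an estimated correlation and with fry, whose smallest adjusted p-values were 0.276, 0.355 and 0.583. With at least 20 cells they numbered 14 for olanzapine against placebo and 14 for haloperidol against olanzapine. Leaving out each mouse gave 10 to 22 lists for haloperidol against placebo, 20 to 27 for olanzapine against placebo and 14 to 27 for haloperidol against olanzapine.

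Some called lists turned in direction. Ribosomal genes in astrocytes, with a median of -0.0647 for haloperidol against placebo, were called the other way without the 4 mice (0.146, adjusted p = 0.00736). They also turned, uncalled, without haloperidol 2 (0.0465) or placebo 5 (0.0783; each mouse left out, -0.202 to 0.0783). For haloperidol against olanzapine their median was 0.118, and 0.0199 with at least 20 cells and 0.0332 without haloperidol 4, where the direction of the test turned and the median did not. Without haloperidol 3 it was -0.0645 (each mouse left out, -0.0645 to 0.306). In neurons and without the 4 mice, ribosomal genes went from -0.133 to 0.0824 for haloperidol, a call the other way (adjusted p = 0.0305; each mouse left out, -0.334 to -0.00847). For olanzapine they went from -0.108 to 0.0292, uncalled (-0.268 to 0.000193). Oxidative phosphorylation genes went from -0.119 to -0.0418 for haloperidol (-0.175 to -0.0436), where the direction of the test turned and the median did not. With doublets kept, oxidative phosphorylation genes in neurons went from 0.0732 to -0.0567 for haloperidol against olanzapine (0.00305 to 0.208).

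Class shares with an exact p under 0.05 numbered 0 for haloperidol against placebo (1 with clusters at resolution 2, 0 to 2 with each mouse left out: 1 without placebo 2 and 2 without haloperidol 5). For olanzapine against placebo the 2 shares became 1 on a centred log-ratio scale, 1 with the stricter cell filter, 0 with doublets kept and 0 without the 4 mice, and 1 to 3 with each mouse left out. For haloperidol against olanzapine they numbered 0 to 2. The mean correlation of the drugs' fold changes was 0.0459 with the placebo mice split. No paired analysis was possible because the replicate numbers follow the order of deposit and mark no shared animal, litter or day. The comparison of direct- and indirect-pathway neurons and its alternatives were not run. In the class other a mouse in the fit held 33277 to 249324 UMIs, and in simulated counts of that depth 34.3 to 37.3% of 2-fold changes against placebo were recovered, so most changes of that size would be missed.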

Other observations

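In this part, the splits of the mice and the endothelial-like class were chosen after the results were seen. In endothelial-like cells 1 gene was called with olanzapine: Adamts1, a secreted protease gene that restrains vessel growth, rose from 150 ± 64.7 CPM with placebo (SD, n = 4) to 585 ± 117 CPM (SD, n = 3), a log2 fold change of 2.02 ± 0.33 (edgeR adjusted p = 0.00467). In neuroblasts the fixed markers of cycling progenitors were higher with both drugs than in the shared placebo mice, whose score had an SD of 1.48, more than its difference from either drug (7.93 against 8.83 and 8.67). Medians were 0.43 for haloperidol (5 of 5 higher, adjusted p = 0.00216; adjusted p = 0.632 with an estimated correlation) and 0.44 for olanzapine (5 of 5 higher, adjusted p = 0.0200; adjusted p = 0.628 with an estimated correlation). Of these markers 0 passed over all genes tested or adjusted over the list alone. In neurons, clock genes rose with olanzapine (6 of 7 higher, median 0.41, adjusted p = 0.0130; adjusted p = 0.447 with an estimated correlation), and Hlf (1.15 ± 0.34) was the 1 member that passed adjusted over the list alone, with 0 over all genes tested. The call was lost without placebo 2 (adjusted p = 0.0593), placebo 4 (0.0602) or olanzapine 4 (0.108).

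The labels give 500 cells loaded per mouse, and 4 mice hold more deposited cells than that: placebo 5 (514), olanzapine 5 (582), haloperidol 3 (630) and olanzapine 3 (1189). Without olanzapine 3 the olanzapine count fell to 0, as it did without placebo 2.

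Immediate early genes were higher with olanzapine in neurons and in the class other. Handling of the tissue before lysis, which may induce these genes in every cell of a mouse, was tested by whether their scores move together in neurons and astrocytes once group means are removed. Over 15 mice and 4 shared members, Pearson's r was 0.305 (permutation p = 0.279, adjusted p = 0.279 over 3 relations), Spearman's rho was 0.136 (permutation p = 0.632), and r was 0.179 without the 2 mice farthest from the median. The other relations were closer, over 13 mice: r was 0.474 for neurons and microglia (rho 0.549, permutation p = 0.0546; adjusted p of r 0.204) and 0.441 for astrocytes and microglia (rho 0.467, permutation p = 0.110; adjusted p of r 0.204). With so few shared members these values neither show nor exclude handling, so it cannot be told apart from an effect of olanzapine.

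Chance could not be excluded for the counts of genes called against placebo or for any count of lists. Among 100 splits of the 10 mice of each pair of groups, the real one included, 20 called at least the 2 genes of haloperidol against placebo (highest other split 26) and 6 at least the 10 genes of olanzapine against placebo (highest other 18). Between the drugs 0 genes were called, which every split reaches, so the 100 of 100 splits decide nothing there (highest other 33). For lists, 61 splits called at least 15 for haloperidol (highest other 28), 18 at least 24 for olanzapine (highest other 39) and 27 at least 22 between the drugs (highest other 37). The median of the other splits was 0 genes in each comparison. For lists it was 16 for haloperidol against placebo, 17 for olanzapine against placebo and 16 between the drugs. The splits with 26 and 33 genes, against real counts of 2 and 0, are the highest of each set. They may reflect a structure of the samples, which the labels do not name and no test here addressed.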
